A study of Escherichia coli with 3 samples.

How the data were processed

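Transcript levels were measured on 2-colour spotted DNA arrays in 3 strains of Escherichia coli, the wild type W3110 and mutants lacking gshA or gshB. These genes encode the enzymes of the first and the last step of glutathione synthesis. Per the labels' protocols, cultures grew at 37 °C in a mineral salt medium with 0.2 % glycerol and 0.3 % casamino acids to a turbidity of 100 Klett, and cadmium-treated cells then received 100 µM cadmium chloride for 10 min. RNA of treated and of untreated cells of a strain was reverse-transcribed with Cy3 or Cy5 dCTP and hybridised together on 1 slide. Per the series' design text, the repeats were independent biological ones. The labels hold 1 entry per strain with 3 slides each, so n is 3 slides per strain and 9 in all, and slide numbers only name slides.

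The deposited scanner values are spot intensity on a linear scale, not normalized, written by ImaGene 4.2 per the file headers, with foreground and local background mean and median, standard deviations and a spot flag. Each slide and dye was scanned at several gains, which gave 71 sets of values. Gain 40 was incomplete, since the Cy3 values of 1 slide of the gshA mutant at that gain were not analysed here. The deposited value table holds 1 column per strain of the authors' processed log2 ratios. Its scale was found from the values, of which 99.7 % per column were the log2 of a ratio rounded to 2 decimals within a tolerance of 0.05 %. How the authors normalized these ratios is not given in the sources used here. The medians of the columns were -0.690 for the wild type, -0.474 for the gshA mutant and -0.600 for the gshB mutant, so they were not centred on 0.

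The labels place untreated cells in Cy3 and treated cells in Cy5 throughout, while the label protocol names either dye. As labelled, log ratios of slides of one strain correlated at 0.824 to 0.858 in 3 pairs and at -0.51 to -0.272 in the other 6. Every negative pair held wild type slide 1, gshA mutant slide 3 or gshB mutant slide 3. When each column of the authors' table was regressed on the log ratios of its 3 slides, these 3 slides had negative weights (-0.335, -0.332 and -0.363) and the other 6 positive weights (0.261 to 0.444). The 3 slides were therefore read as carrying treated cells in Cy3, and their sign was turned, which gave ratios of cadmium over untreated. The direction of these slides rests on the authors' table and the correlations and is not stated by the labels. Cy5 over Cy3 on every slide was the test fixed before the data were examined, and turning slides was planned as an alternative. The turned values became the values reported after the table had been set against the slides, and results as labelled are given beside them. The direction of the value table itself is likewise inferred. Its correlation with the fitted ratios over probes (0.911, 0.897 and 0.932) is not independent of the turning. Of each strain, 2 slides run as labelled and 1 the other way, so a part of any dye effect stays in the mean of a strain, whereas an effect common to all slides cancels in differences between strains. A dye effect passed the threshold for 2291 probes (54.4 %), with a standard deviation of 0.557 against 0.860 for the mean response.

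The gain was chosen by the smallest sum of saturated and dim shares. Saturated spots (65000 or above) made up 0.00241 % at gain 30, 0.406 % at gain 50 and 1.96 % at gain 60. Spots not above background (foreground median at or below the background median plus 2 background standard deviations) made up 23.3 %, 13.1 % and 12.8 %. Gain 50 was used. Each slide held 4608 spots in 16 print blocks, of which 322 control spots had weight 0 in loess and were left out of tests. Spots of a probe were averaged (73 probes had 2 spots), which left 4213 probes. Spots with a flag were kept. Foreground medians were corrected by normexp with offset 50, and log ratios were normalized within slides by global loess (span 0.3, 4 iterations) with no scaling between slides. Single-channel levels came from the same values after Aquantile. The arrays' build is not given in the sources used here. Probe identifiers are locus tags, of which 4057 matched a table of the MG1655 assembly ASM584v2 used for gene symbols, and 156 kept their identifier. The headers show that wild type slide 1 was quantified on another day than the other slides at gain 50. A block for that day would take up this slide alone, so the fit without it is the fit within 1 day.

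Log ratios of all 9 slides were fitted in limma 3.58.1 under R 4.3.3 with a mean per strain, no covariate and empirical Bayes moderation (6 residual and 3.53 prior degrees of freedom). Each strain's response, their mean and the differences between strains were tested two-sided against 0, with Benjamini-Hochberg adjustment over 4213 probes and a threshold of 0.05. All values given as adjusted p for genes come from limma. Levels of gshA and gshB were tested on the mean of both channels, and untreated levels on the untreated channel. Strains were not on the same slide, so tests of levels compare slides as well as strains. A gene saturated in the cadmium channel on all 3 slides of a strain has a lower bound of its rise, taken from Aquantile levels, which are open to dye bias because the orientations are unbalanced. This bound equals the fitted mean ratio, so it carries the error of the fit and can be undercut by another fit.

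Gene lists (22 lists, 554 members, 547 measured) were fixed from general knowledge of E. coli regulons. They cover zinc and cadmium homeostasis, copper homeostasis, heat shock, the SoxRS and MarA response, the OxyR peroxide response, iron-sulfur cluster assembly, iron uptake, cysteine and sulfate assimilation, methionine biosynthesis, glutathione and thiol redox, envelope stress, the SOS response, ribosomal proteins, flagella and chemotaxis, general stress and acid resistance (RpoS), the respiratory chain with ATP synthase, the TCA cycle, arginine, histidine, branched-chain amino acid, and purine and pyrimidine biosynthesis, and anaerobic metabolism. Some genes stand on more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation, with fry and with fry's mixed test. Genes named are gshA, gshB and zntA, the 12 largest rises and falls of each strain (adjusted p under 0.05, same sign on all 3 slides, above background in a channel), up to 8 in each direction for a difference and up to 4 members of each list by adjusted p. Members that moved against the name of their list, the members behind small counts, and the trp, mtr, frm, ars, pro, tau and ssu genes treated as operons were named after their values were seen.

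On simulated slides with 4213 genes, the wild type test recovered 22.4 % of 67 genes changed by 1 log2 unit, 68.7 % of 67 changed by 2 and 93.9 % of 66 changed by 3. For the gshA mutant minus wild type it recovered 2.99 %, 46.3 % and 75.8 %. With a dye term the shares were 68.7 %, 91.0 % and 100 % for the wild type and 40.3 %, 86.6 % and 97.0 % for the difference. The simulated dye effect and independent noise came from a fit with a dye term, so better recovery with that term was built in. Genes were changed on the wild type slides only, unlike the real responses, which the strains share. Alternatives covered gain, spot measure, background correction, normalization within and between slides, dim and marked spots, the variance model, array weights, the slides in the fit, each slide left out, dye orientation, the set test and the authors' value table. A dye term, the 6 slides with cadmium in Cy5 alone, the lists with the dyes as labelled and the Cy3 channel of every slide as untreated were added after seeing the data. The number of slides limits the precision of every value.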

Results

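The response of Escherichia coli to 100 µM cadmium for 10 min was measured in the wild type and in the gshA and gshB mutants, each with 3 slides that set treated against untreated cells. The median spot signal of a slide lay between 497.5 and 760.5 in Cy3, over a local background of 58 to 117, and between 370.5 and 866 in Cy5, over 83 to 207. Probes not above background made up 0.770 to 1.80 % in Cy3 and 13.2 to 27.1 % in Cy5, and 4 to 45 probes per slide and dye were saturated. In Cy3 the control spots too were mostly above background (89.8 % and 96.0 %), so passing there is weak evidence of signal. As read here, Cy5 held cadmium on 2 slides of each strain and untreated cells on 1. A gene not above background in the cadmium channel of 2 slides may thus be so wherever Cy5 carried cadmium. The direction of 1 slide per strain is inferred, because as labelled these slides correlated negatively with the others of their strain. Ratios are cadmium over untreated with these slides turned, and counts as labelled stand beside each comparison.

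The deleted genes were examined first. The gshA probe (B2688), for glutamate-cysteine ligase, had a level of 8.44 ± 0.562 (log2 intensity, SD, n = 3) in the gshA mutant and 11.98 ± 0.306 in the wild type, a difference of -3.55 (SE 0.343, adjusted p = 0.0110). In the gshB mutant it differed from the wild type by 0.00 (adjusted p = 0.999). The gshB probe (B2947), for glutathione synthetase, had a level of 7.02 ± 0.291 in the gshB mutant and 9.68 ± 0.179 in the wild type, a difference of -2.65 (SE 0.233, adjusted p = 0.00485). In the gshA mutant it differed by 0.01 (adjusted p = 0.997). At gain 30, where more spots are dim, the difference of gshB was -1.14 and did not pass (adjusted p = 0.080). The gshB probe in its mutant was not above background in 1 channel of each slide, which was Cy5 each time. The gshA probe in its mutant was above background in both channels of every slide, Cy5 included, so some signal remained there.

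In the wild type, transcripts for chaperones, thiol redox proteins and the zinc and cadmium exporter rose. zntA (B3469), the exporter of zinc, cadmium and lead, rose 8.75-fold (log2 3.13, SE 0.377, n = 3, adjusted p = 0.000989). grxA (B0849), for glutaredoxin 1, rose 78.6-fold (log2 6.30, SE 0.227, adjusted p = 8.14e-07). The small heat shock protein genes ibpB (B3686) and ibpA (B3687) were saturated in the cadmium channel on all 3 slides and rose at least 226-fold and 113-fold, while bhsA (B1112) rose at least 59.6-fold and the catalase gene katG (B3942) at least 30.01-fold (adjusted p of 1.22e-05 to 5.42e-05 for these 4). The fitted log2 ratio of ibpB was 7.82 (SE 0.560), and 7.73 with a dye term. Other large rises, in log2, were those of trxC (thioredoxin 2, 5.45), marA (a regulator of multidrug resistance, 5.37), yjgH (5.29), sbp (sulfate-binding protein, 5.26), bdcA (5.23), ynjF (5.02) and marR (the repressor of marA, 4.92).

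Falls in the wild type were led by exbB (B3006) and exbD (B3005), which energise iron-siderophore import with TonB and changed by -4.70 (SE 0.502, adjusted p = 0.000467) and -4.66 (SE 0.613, adjusted p = 0.00160) in log2. feoA, of ferrous iron uptake, changed by -3.91, and exbB and feoA were not above background in the cadmium channel of 2 slides. pyrD (B0945), for dihydroorotate dehydrogenase, changed by -4.44 (SE 1.07, adjusted p = 0.0349) and carA, for carbamoyl phosphate synthetase, by -3.75. Further falls were those of slp (-3.55), flgD of the flagellar hook (-3.52), glpF, the glycerol channel (-3.46), dctA, a dicarboxylate transporter (-3.40), nmpC, an outer membrane porin (-3.28), flhD, a master regulator of flagella (-3.20), and codB, a cytosine transporter (-3.11). In all, 282 of 4213 genes passed, 168 higher and 114 lower, and 274 of them changed at least 2-fold. As labelled, with no slide turned, 189 passed (79 higher, 110 lower), and with a dye term 828. The count was 152 without slide 1 and 110 without slide 3 of the wild type.

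Of the 22 lists 12 passed in the wild type at the preset correlation (2 as labelled), and 4 of them also with an estimated correlation. Heat shock genes rose in 19 of 30 measured members and fell in 0 (27 up, adjusted over the list alone), including ycjX (3.00) and the protease gene lon (2.62, SE 0.233), with adjusted p = 1.89e-23 for the list and 0.000777 with an estimated correlation. Cysteine and sulfate assimilation genes rose in 18 of 33 (23 adjusted over the list alone), among them cbl, a regulator of sulfonate use (4.63), cysN (4.21) and cysD (3.71, saturated in the cadmium channel of 2 slides) of sulfate activation and cysH (4.04) of sulfite formation (list adjusted p = 2.63e-20, and 0.0385 with an estimated correlation). Glutathione and thiol redox genes rose in 13 of 32 (14 adjusted over the list alone), with nemA (3.98), frmA (4.00) and frmR (4.22), both saturated in the cadmium channel of 1 slide, after grxA (list adjusted p = 9.87e-13, and 0.0229 with an estimated correlation). Flagellar and chemotaxis genes fell in 13 of 51 and rose in 1, fliI (1 up and 16 down adjusted over the list alone), with fliF at -2.38 and fliZ at -1.48 (list adjusted p = 8.32e-09, and 0.0385 with an estimated correlation). In the cadmium channel fliF was not above background on 2 slides and fliZ on 1.

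A further 8 lists passed in the wild type only at the preset correlation. Members of the OxyR peroxide response rose in 9 of 16 (9 up and 3 down adjusted over the list alone), such as hemH (4.34) and ahpF (at least 20.6-fold, saturated in the cadmium channel on all 3 slides), while fhuF, a ferric iron reductase, changed by -2.96 and oxyR, the regulator itself, by -1.30 (list adjusted p = 1.62e-07, and adjusted p = 0.0839 with an estimated correlation). SoxRS and MarA genes rose in 8 of 26 and fell in 1, ybjC (-1.56), of the operon with the nitroreductase gene nfsA (9 up and 3 down adjusted over the list alone), with acnA at 2.61 and inaA at 2.28 (adjusted p = 0.0839 with an estimated correlation). Iron-sulfur cluster assembly genes rose in 5 of 16 (11 adjusted over the list alone), including iscR (2.68) and, saturated on 1 slide each, iscU (2.29) and nfuA (1.98), with adjusted p = 0.158 with an estimated correlation. Iron uptake genes fell in 7 of 37 (1 up and 13 down adjusted over the list alone), bfd among them at -3.07, not above background in the cadmium channel of 1 slide (adjusted p = 0.0839 with an estimated correlation). Purine and pyrimidine genes fell in 3 of 21, pyrD, pyrC (-1.995) and purT (-1.49), and in 13 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). SOS genes rose in 2 of 22, the polymerase gene polB (3.02) and the Holliday junction helicase gene ruvB (1.81), and in 2 adjusted over the list alone (adjusted p = 0.351 with an estimated correlation). Respiratory genes held 1 rise, ndh (3.45), for the NADH dehydrogenase that pumps no protons, and 1 fall, sdhC of succinate dehydrogenase (-1.65, saturated in the untreated channel of 1 slide), with 1 and 5 adjusted over the list alone (adjusted p = 0.0839 with an estimated correlation). Ribosomal protein genes passed in 0 of 54 in limma, also adjusted over the list alone, with a list median of -0.76 (adjusted p = 0.351 with an estimated correlation).

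The other 10 lists did not pass in the wild type. Zinc and cadmium homeostasis held 2 rises among 14, zntA and its activator gene zntR (2.86) (list adjusted p = 0.140). General stress and acid resistance held 1 rise among 31, dps (at least 3.62-fold), and 3 falls, gadE (-2.89), slp and gadX (-2.05) of acid resistance, with gadE not above background in the cadmium channel of 2 slides. Arginine genes held the rises of argE (1.39) and artQ (1.57) and the fall of carA, with a median of 0.11 but a mean of -0.21 and a test that pointed down (adjusted p = 0.782). Envelope stress held 1 fall among 24, ppiA (-1.25). Copper, methionine, TCA cycle, histidine, branched-chain amino acid and anaerobic metabolism lists held 0 members that passed in limma. Their adjusted p were 0.594, 0.373, 0.916, 0.0657, 0.339 and 0.426.

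**Figure D1:**
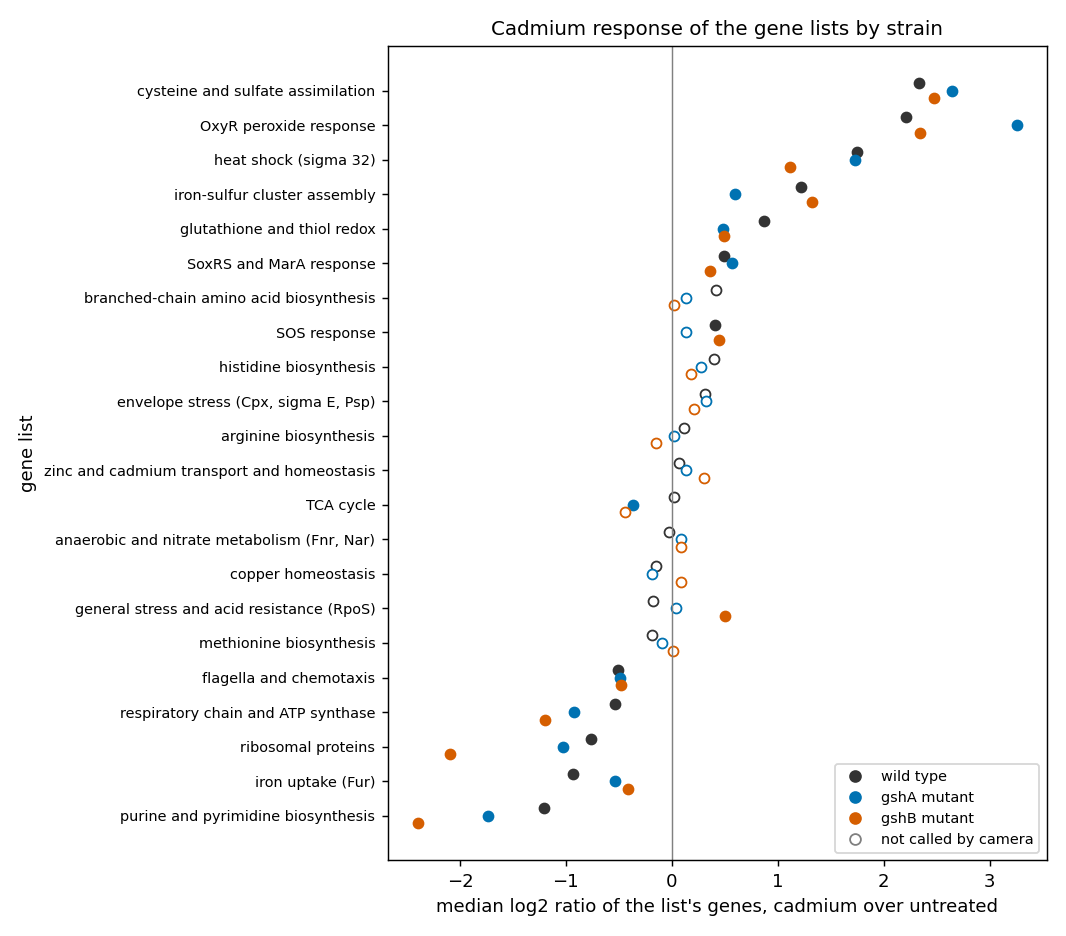
Median log2 ratio of cadmium over untreated (x axis) of the 22 gene lists (y axis) in each strain, filled where camera called the list at the preset correlation and open where it did not. Ribosomal proteins lay at -0.76 in the wild type, -1.02 in the gshA mutant and -2.09 in the gshB mutant.

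In the gshA mutant, which lacks the enzyme that makes glutamylcysteine, the largest rises included ibpB (log2 7.56), ibpA (7.11), yjgH (6.28), bdcA (6.05), grxA (5.93, SE 0.227, n = 3, adjusted p = 1.44e-06), sbp (5.84), bhsA (5.76), ynjF (5.58), trxC (5.47), marR (5.33) and katG (5.26), of which ibpA, ibpB, trxC, marR and katG were saturated in the cadmium channel of 2 slides and yjgH and bhsA of 1. trpE (B1264), for anthranilate synthase, saturated on 1 slide, rose by 5.20 (SE 0.431, adjusted p = 9.67e-05). zntA rose 9.05-fold (log2 3.18, SE 0.377, adjusted p = 0.000850). The largest falls were those of nmpC (-5.31, SE 0.610, adjusted p = 0.000709, not above background in the cadmium channel of 1 slide), carA (-4.60), exbD (-4.33), aldA, for aldehyde dehydrogenase A (-3.87), glpF (-3.82), mepS, a murein endopeptidase gene (-3.69), flgD (-3.65), flhD (-3.52), cdd and ndk of nucleoside metabolism (both -3.05), rihA (-2.93) and dctA (-2.92). Of 4213 genes 303 passed, 181 higher and 122 lower, and 290 changed at least 2-fold. As labelled 108 passed (54 higher, 54 lower), and with a dye term 935. The count was 144 without slide 1 and 114 without slide 2 of the gshA mutant, and 131 when slides of this strain alone entered the fit.

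Heat shock genes rose in 19 of 30 in the gshA mutant (24 adjusted over the list alone) and cysteine and sulfate genes in 23 of 33 (28 adjusted over the list alone), with cysH at 4.79 and cbl at 4.76. Glutathione and thiol redox genes rose in 10 of 32 (11 adjusted over the list alone), such as gor, for glutathione reductase (3.06). Respiratory genes fell in 9 of 34, for example sdhC (-2.46), sdhA (-2.09) and atpE of ATP synthase (-2.29), and rose in 1, ndh (3.00), with 1 and 17 adjusted over the list alone. These 4 lists of the 12 that passed at the preset correlation (8 as labelled) passed at both, with adjusted p = 0.000963, 0.0367, 0.0367 and 0.0367 with an estimated correlation. OxyR members rose in 9 of 16, among them yaaA (4.63), and oxyR fell by 1.72 (9 up and 3 down adjusted over the list alone, adjusted p = 0.0760 with an estimated correlation). SoxRS and MarA genes rose in 7 of 26, including soxS (2.48), and fell in 2, ybjC and the nitroreductase gene nfsA (10 up and 3 down adjusted over the list alone, adjusted p = 0.0827 with an estimated correlation). Flagellar genes fell in 11 of 51 and rose in 1, fliI (1 up and 14 down adjusted over the list alone, adjusted p = 0.0626 with an estimated correlation). Purine and pyrimidine genes fell in 9 of 21, such as pyrB (-2.22, saturated in the untreated channel of 1 slide) and pyrI (-2.60) of aspartate transcarbamoylase (11 adjusted over the list alone, adjusted p = 0.0857 with an estimated correlation).

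Ribosomal protein genes fell in 7 of 54 in the gshA mutant, with rpsR at -2.46 and rplI at -2.56 (17 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation). Iron uptake genes fell in 3 of 37, exbD, bfd (-2.25) and feoA (-2.21) (3 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation). In the cadmium channel feoA was not above background on 2 slides and bfd on 1. Iron-sulfur assembly genes rose in 4 of 16, nfuA (1.53), iscR (1.99), iscA (1.68) and iscU (1.36) (5 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation). In the TCA cycle list sucA fell by 1.53, 1 of 13 also adjusted over the list alone (list adjusted p = 0.0353, and adjusted p = 0.341 with an estimated correlation). Lists that did not pass held the rise of zntA (zinc and cadmium), of polB and ruvB (SOS, adjusted p = 0.110), of dps (RpoS, at least 10.96-fold) and of argE and artQ, and the falls of metK, for S-adenosylmethionine synthetase (-1.97), carA and carB. For RpoS genes the median was 0.04 and the test pointed up but the mean was -0.00, and for arginine genes the median was 0.02 but the mean -0.36 and the test pointed down. Copper, envelope stress, histidine, branched-chain amino acid and anaerobic lists held 0 members that passed in limma (list adjusted p = 0.653, 0.330, 0.232, 0.898 and 0.653).

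In the gshB mutant, which lacks the enzyme that turns glutamylcysteine into glutathione, tauA (B0365) and tauB (B0366), of taurine uptake, rose by 6.16 (SE 0.465, n = 3, adjusted p = 7.91e-05) and 5.62 (SE 0.581, adjusted p = 0.000332) in log2, and both were not above background in the untreated channel of 1 slide. Other large rises were those of ibpB (6.97), yjgH (6.30), ibpA (6.09), grxA (5.82), trxC (5.75), ynjF (5.62), sbp (5.34) and bdcA (4.87), of which ibpB and ibpA were saturated in the cadmium channel of 2 slides and trxC of 1. bhsA rose at least 57.6-fold and katG at least 38.0-fold. zntA rose 11.2-fold (log2 3.49, SE 0.377, adjusted p = 0.000447). Falls were led by pyrD (-5.78, SE 1.07, adjusted p = 0.00564), nmpC (-5.21), purM (B2499) of purine synthesis (-5.19, SE 0.628, adjusted p = 0.000766), carA (-5.03), tsgA (-4.80), ndk (-4.74), hflD (-4.30), aldA (-4.24), mepS (-4.18), mipA (-4.13), codB (-4.12) and pyrC (-4.06). On 1 slide pyrD was not above background in the cadmium channel and mepS was saturated in the untreated one. Of 4213 genes 752 passed, 358 higher and 394 lower, and 673 changed at least 2-fold. As labelled 145 passed (79 higher, 66 lower), and with a dye term 1558. The count was 351 without slide 1 and 326 without slide 2 of the gshB mutant.

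In the gshB mutant 13 lists passed at the preset correlation (4 as labelled). Ribosomal protein genes fell in 37 of 54, with rplK at -3.41, rplA at -3.33 and rpmH at -3.52 (45 adjusted over the list alone, list adjusted p = 2.35e-19, and adjusted p = 0.141 with an estimated correlation). Purine and pyrimidine genes fell in 17 of 21, purC (-3.67) and purA (-1.73) among them (18 adjusted over the list alone, adjusted p = 0.0956 with an estimated correlation). Respiratory genes fell in 15 of 34, such as sdhC (-3.63) and sdhD (-3.66), and rose in 1, ndh, with 2 and 18 adjusted over the list alone (adjusted p = 0.0955 with an estimated correlation). Heat shock genes rose in 16 of 30, clpB at 2.81 for example (18 adjusted over the list alone), and this list passed with both correlations (adjusted p = 1.19e-10, and 0.00880 with an estimated correlation). Cysteine and sulfate genes rose in 20 of 33 and fell in 1, cysZ (-1.03), for a sulfate transporter (23 up and 1 down adjusted over the list alone, adjusted p = 0.0956 with an estimated correlation). Glutathione and thiol redox genes rose in 11 of 32, such as gor (2.59) and yqhD (3.98), and fell in 1, cydD (-0.82), of a thiol exporter (12 up and 2 down adjusted over the list alone, adjusted p = 0.107 with an estimated correlation). RpoS genes rose in 9 of 31, including sodC (2.38), talA (2.24) and osmY (1.83), and fell in 3, slp, gadX and gadE (11 up and 3 down adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). In the cadmium channel yqhD was saturated on 2 slides and purC not above background on 1, and sdhC was saturated in the untreated channel of 1.

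OxyR members rose in 9 of 16 in the gshB mutant and fell in 2, oxyR (-1.24) and dsbG, for a periplasmic disulfide isomerase (-1.09) (9 up and 3 down adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). SoxRS and MarA genes rose in 9 of 26, soxR (2.42) among them, and fell in 3, the superoxide dismutase gene sodA (-2.01), ybjC (-1.61) and yggX (10 up and 4 down adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). Iron-sulfur assembly genes rose in 8 of 16, such as sufA (3.27) (10 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Iron uptake genes fell in 4 of 37, exbB (-3.51), exbD (-3.73), bfd (-1.95) and feoA (-1.91) (4 adjusted over the list alone, adjusted p = 0.435 with an estimated correlation). In the cadmium channel exbB, bfd, feoA and oxyR were not above background on 1 slide each. SOS genes rose in 5 of 22, polB (3.57) and sbmC (1.39) among them (5 adjusted over the list alone, adjusted p = 0.402 with an estimated correlation). Flagellar genes fell in 14 of 51 and rose in 1, fliI (1 up and 16 down adjusted over the list alone, adjusted p = 0.138 with an estimated correlation). In lists that did not pass, zntA, zntR and zraP rose and znuA, of zinc uptake, fell by 1.89, 4 envelope stress genes rose (rpoE, 1.71) and 3 fell (ppiA, -2.02), sucA, sucB and aceB of the TCA list fell, argE and ilvD rose, and carA, carB and artI fell. Copper, methionine, histidine and anaerobic lists held 0 members that passed in limma (list adjusted p = 0.732, 0.732, 0.526 and 0.488), and for methionine genes the median was 0.01 but the mean -0.12 and the test pointed down.

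**Figure D2:**
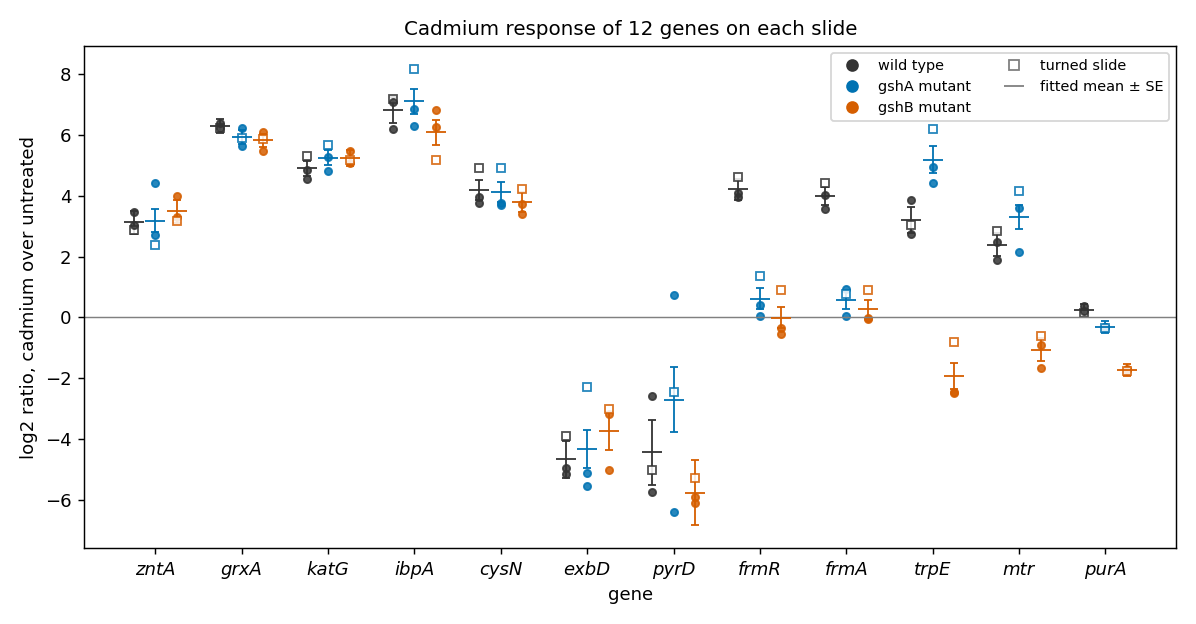
Log2 ratio of cadmium over untreated (y axis) of 12 genes on each slide of the 3 strains, with turned slides as open squares and the bar and error bar giving the fitted mean and its SE. zntA stood at 3.13, 3.18 and 3.49 in the wild type, gshA mutant and gshB mutant, while trpE stood at 3.21, 5.20 and -1.92.

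Averaged over the strains, 1196 genes passed, 586 higher and 610 lower, of which 562 changed at least 2-fold. Of the 22 lists 12 passed at the preset correlation (6 as labelled) and 4 also with an estimated correlation. Heat shock genes rose in 26 of 30 (29 adjusted over the list alone, adjusted p = 0.00204 with an estimated correlation). Cysteine and sulfate genes rose in 27 of 33 (27 adjusted over the list alone, adjusted p = 0.0491 with an estimated correlation). Respiratory genes fell in 22 of 34 and rose in 1 (2 up and 24 down adjusted over the list alone, adjusted p = 0.0491 with an estimated correlation). Passing only at the preset correlation, iron-sulfur assembly genes rose in 13 of 16 (15 adjusted over the list alone), ribosomal protein genes fell in 41 of 54 (46) and purine and pyrimidine genes in 19 of 21 (20), with adjusted p = 0.210, 0.163 and 0.0803 with an estimated correlation. Rises called in all 3 strains numbered 126, against 0.613 for independent lists of these sizes, and shared falls 67, against 0.309. The strains shared an estimate of the spread per gene and part of any dye effect, so the values for independent lists are no test of a shared response. Responses correlated across genes at 0.887 between the wild type and the gshA mutant, 0.817 between the wild type and the gshB mutant and 0.808 between the mutants, although genes are not independent and a dye effect common to the slides adds to each. With a dye term these values were 0.888, 0.811 and 0.803. As labelled 1251 genes passed for the mean (617 higher, 634 lower), and with a dye term 2009.

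Whether a lack of glutathione alters the response was tested by the differences between strains. frmR (B0357) and frmA (B0356), for the repressor and the formaldehyde dehydrogenase of the glutathione-dependent formaldehyde pathway, rose by 4.22 (SE 0.349, n = 3, adjusted p = 0.000107) and 4.00 (SE 0.294, adjusted p = 6.15e-05) in the wild type. In the gshB mutant they stood at -0.00 and 0.27, and the difference from the wild type was -4.22 (SE 0.494) for frmR and -3.73 (SE 0.416) for frmA (both adjusted p = 0.0144). These values of the gshB mutant are not exact, since frmR was saturated in the cadmium channel of 2 slides and frmA of 3, and both in the untreated channel of 1. In the gshA mutant they stood at 0.61 and 0.58, and differences of -3.60 (SE 0.494, adjusted p = 0.0716) and -3.43 (SE 0.416, adjusted p = 0.0517) did not pass. There the cadmium channel was saturated on 1 slide for each, and the untreated channel on 1 for frmR and 2 for frmA. With a dye term both passed (adjusted p = 0.000278 and 0.000990), and frmR and frmA rose by 0.78 and 0.68 in the gshA mutant (adjusted p = 0.0121 and 0.0434). At gain 30, with 0 saturated readings of frmR and frmA, they stood at 0.25 and 0.47 in the gshA mutant (adjusted p = 0.547 and 0.304) and at 0.53 and 0.54 in the gshB mutant (adjusted p = 0.0541 and 0.138), and 0 of these passed. At this gain both mutants differed from the wild type, frmR by -3.79 and -3.51 (adjusted p = 0.000106 and 0.000219) and frmA by -3.46 and -3.40 (adjusted p = 0.00169 and 0.00133) in the gshA and gshB mutant. Over all alternatives the adjusted p of the difference between the gshB mutant and the wild type ranged from 4.9e-05 to 0.9999 for frmR and from 0.000102 to 0.9999 for frmA, with differences of -4.67 to -1.74 and -4.04 to -1.38. These ranges include the fit with the dyes as labelled, in which 0 of 86 named values kept their call. The calls of frmR and frmA were lost in 9 of 27 alternatives each, so not in that fit alone.

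trpE rose by 3.21 (adjusted p = 0.00172) in the wild type, where it was saturated in the cadmium channel of 1 slide, and fell by 1.92 (adjusted p = 0.0142) in the gshB mutant. The difference of the gshB mutant was -5.13 (SE 0.609, adjusted p = 0.0144) from the wild type and -7.11 (SE 0.609, adjusted p = 0.00247) from the gshA mutant. mtr (B3161), a tryptophan transporter gene, stood at 2.40, 3.31 and -1.06 in the wild type, gshA and gshB mutant, and differed between the mutants by -4.37 (SE 0.547, adjusted p = 0.0335). mipA (B1782), of murein synthesis, stood at -1.47, -0.97 and -4.13 and differed between the mutants by -3.16 (SE 0.433, adjusted p = 0.0475). purA (B4177), for adenylosuccinate synthetase, stood at 0.25, -0.32 and -1.73 and differed between the gshB mutant and the wild type by -1.97 (SE 0.280, adjusted p = 0.0479). Under 27 alternatives the differences of purA (-2.02 to -0.69) and mipA (-3.78 to -1.53) lost their call in 18 each and that of mtr (-4.94 to -1.20) in 12. Those of trpE lost it in 9 from the wild type (-5.77 to -2.56) and 2 from the gshA mutant (-7.67 to -2.44). The ranges again include the fit with the dyes as labelled.

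In all, 0 genes differed in limma between the gshA mutant and the wild type (56 at an unadjusted p under 0.05), 4 between the gshB mutant and the wild type and 3 between the mutants. As labelled each of these counts was 0, and with a dye term they were 4, 79 and 93. The 4 genes of the gshA mutant with a dye term were frmR, frmA, proV and nlpI. Without any 1 slide of the wild type, or without slide 1 or 2 of the gshB mutant, 0 genes differed between the gshB mutant and the wild type. The count between the mutants fell to 1 without slide 2 or 3 of the wild type, slide 2 of the gshA mutant, or slide 1 or 2 of the gshB mutant, and was 6 without slide 3 of the gshB mutant.

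For lists, the RpoS genes had a higher response in the gshB mutant than in the wild type (median difference 0.87), which passed at the preset correlation (adjusted p = 2.66e-14), with an estimated correlation (adjusted p = 0.0418) and in fry (adjusted p = 0.0474). No single RpoS gene passed for this difference, where the 4 that did were trpE, frmR, frmA and purA. The same list stood lower in the untreated gshB mutant than in the untreated wild type (median -0.39). Untreated readings are part of the ratios, so both results are not independent. Ribosomal protein genes had a lower response in the gshB mutant than in the wild type (median difference -1.22, adjusted p = 6.8e-17, and adjusted p = 0.209 with an estimated correlation). Purine and pyrimidine genes likewise had a lower response (median difference -0.92, 1 down and 4 down adjusted over the list alone, adjusted p = 8.5e-09, and adjusted p = 0.209 with an estimated correlation). Heat shock genes had a median difference of -0.63 (adjusted p = 0.000160, and adjusted p = 0.0552 with an estimated correlation). In the gshA mutant iron-sulfur assembly genes had a lower response than in the wild type (median difference -0.52, adjusted p = 7.52e-07, and adjusted p = 0.366 with an estimated correlation). In all, 9, 9 and 5 lists passed at the preset correlation for the gshA mutant and gshB mutant against the wild type and between the mutants, and 0, 1 and 0 with an estimated correlation. As labelled 3, 3 and 2 lists passed at the preset correlation.

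**Figure D3:**
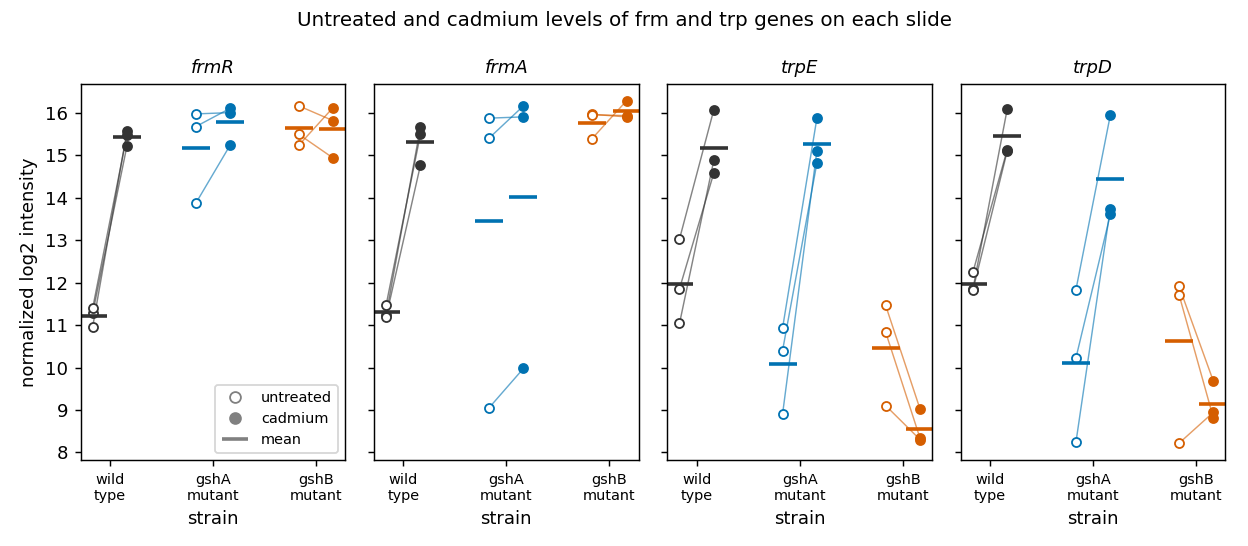
Normalized log2 intensity (y axis) of frmR, frmA, trpE and trpD in untreated (open) and cadmium-treated (filled) cells on each slide, with lines joining the channels of a slide and thick bars at the means. Untreated frmR lay at 11.21 in the wild type, 15.18 in the gshA mutant and 15.63 in the gshB mutant.

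Untreated cells of different strains were compared across slides. frmR was higher in the untreated gshB mutant than in the wild type by 4.42 (SE 0.524, n = 3, adjusted p = 0.0312), at 15.63 ± 0.480 against 11.21 ± 0.224 (SD). It was the 1 gene that passed there, with 42 at an unadjusted p under 0.05 in limma. Between the gshA mutant and the wild type 0 genes passed in limma, with 122 at an unadjusted p under 0.05, and frmR differed by 3.96 (SE 0.524, adjusted p = 0.0526) and gshA by -3.27 (SE 0.446, adjusted p = 0.0526). Both passed at gain 30 (frmR 4.71, adjusted p = 0.000105, and gshA -2.13, adjusted p = 0.00502) and at gain 60 (frmR 2.77, adjusted p = 0.0093, and gshA -3.45, adjusted p = 0.028). They also passed with no background subtraction and with quantile normalization of the untreated channel alone. When a dye term was added frmR passed (adjusted p = 0.0233) and gshA did not (adjusted p = 0.142). Untreated frmR was saturated on 1 slide of each mutant, and on 0 at gain 30. When the Cy3 channel of every slide was taken as untreated, as labelled, 1 gene passed for the gshA mutant and 0 for the gshB mutant, where frmR differed by 3.18. For the gshB mutant the count was 0 without slide 2 or 3 of the wild type or slide 1 or 2 of the gshB mutant, and 2 without slide 1 of the gshA mutant. frmR itself did not pass there without any 1 slide of the wild type or of the gshB mutant (adjusted p of 0.0603 to 0.212). For the gshA mutant the count was 13 without its slide 3 and 1 without its slide 1. In the latter fit frmA passed (4.34, adjusted p = 0.00153), while frmR and gshA did not (adjusted p = 0.152 for each).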

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

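Tests of saturated frm spots and of a dye term in the ratio of calls were chosen only after the results had been seen. Responses to cadmium differed between strains by a test of the difference itself for 7 gene comparisons. As labelled 0 of the 7 passed. Of 27 alternatives the call was lost in 18 each for purA and mipA, 12 for mtr, 9 each for trpE, frmR and frmA against the wild type and 2 for trpE against the gshA mutant. Against the wild type, the response of the gshB mutant differed by -5.13 for trpE, -4.22 for frmR, -3.73 for frmA and -1.97 for purA (log2). Against the gshA mutant it differed by -7.11 for trpE, -4.37 for mtr and -3.16 for mipA.

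frmR and frmA rose in the wild type, while in the mutants they stood between -0.00 and 0.61 at gain 50, where their readings were partly saturated (0.78 and 0.68 in the gshA mutant with a dye term, which passed), and between 0.25 and 0.54 at gain 30, where 0 were saturated and 0 passed. Weak spots on the slides of the mutants would lower both channels, but the median untreated level of frmR, frmA and frmB was higher in the mutants by 3.16 (log2), and that of frmR at gain 30 by 4.71 and 4.52 (adjusted p = 0.000105 and 0.000149). Saturation would narrow the difference at a low gain, but at gain 30 its median over frmA and frmR was -3.49, and at gain 50 with any 1 slide left out it stayed at -3.47 or below, while frmA lay low in both channels of gshA mutant slide 1. A response weakened for all induced genes is argued against by median differences of -0.0510 in the gshA mutant and -0.30 in the gshB mutant over genes called up in the other mutant. Untreated frmA and frmB did not pass in either mutant with all slides. Their differences at gain 30 were 2.58 and 4.66 for frmA and 1.08 and 0.83 for frmB. Without gshA mutant slide 1 frmA passed in both (adjusted p = 0.00153 and 0.000453). In the wild type frmB did not pass at gain 30 (0.48, adjusted p = 0.270), while with a dye term 3 frm genes rose, against 2 without it. A candidate explanation, as a hypothesis found and tested on the same data, concerns frmR, of an operon whose enzyme uses glutathione. It may already be expressed without cadmium in strains that lack glutathione, and for frmA and frmB this is less certain. Untreated levels were compared across slides, whereas an effect of a slide on both channels alike would cancel in the ratios.

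trpE rose in the gshA mutant and fell in the gshB mutant, while trpL and trpD stood at 3.44 and 4.33 in the first and -0.53 and -1.47 in the second. A higher untreated level in the gshB mutant is argued against, since the median untreated difference of these 3 genes, gshB minus gshA mutant, was 0.40 (log2). With any 1 slide left out the median difference of response stayed at -5.08 or below, which argues against a single slide. Of the readings of the 3 genes in the mutants 16.67 % were saturated or not above background, which leaves open how far such spots shaped the size of the difference, although dim treated readings in the gshB mutant and saturated ones in the gshA mutant could have made it smaller. A difference between the strains that goes back to the gshB deletion stays open and untested.

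The gshB mutant had 752 called genes, 2.57 times the mean of the other strains. A dye effect left in the spread widens the pooled spread of all strains alike (median SE 0.342 in each). It might have hidden calls where log ratios are smaller. Their median absolute size was 0.328 in the wild type, 0.316 in the gshA mutant and 0.449 in the gshB mutant. With a dye term the ratio of calls was 1.77, with a range of 1.01 to 2.86 when 1 slide was left out. Wider log ratios on the slides of the gshB mutant stay open too. Scaling between slides would also shrink a truly broader response of this mutant, so it cannot tell such a response from a technical spread. After scaling the ratio was 1.69, with a range of 0.499 to 2.40. Over the other settings it ran from 0.976 as labelled and 1.42 on the 6 slides with cadmium in Cy5 to 3.21 with only the slides of the strains compared, and with 1 slide left out from 1.33 without gshB mutant slide 2 to 3.75 without wild type slide 3, where the strain concerned keeps fewer slides. The low ends of the ranges with 1 slide left out came without a slide of the gshB mutant. That strain then has fewer slides than the others, which by itself can lower its calls. Without a slide of another strain the ratio was 1.69 to 2.86 with a dye term and 1.47 to 2.40 after scaling. These ranges therefore cannot show whether the ratio depends on single slides. A stronger response of this mutant stays open and cannot be told apart from these explanations.

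Gene lists whose response differed at the preset correlation are given by their median difference (log2). For the gshA mutant minus wild type these were -0.52 for iron-sulfur cluster assembly, -0.42 for the respiratory chain, -0.63 for the TCA cycle, 0.38 for iron uptake, -0.16 for glutathione and thiol redox, 0.24 for RpoS genes, -0.31 for ribosomal proteins, 0.16 for cysteine and sulfate assimilation and 0.215 for anaerobic metabolism, with adjusted p of 0.236 to 0.591 with an estimated correlation. For the gshB mutant minus wild type they were -1.22 for ribosomal proteins, 0.87 for RpoS genes, -0.92 for purine and pyrimidine biosynthesis, 0.55 for iron uptake, -0.54 for the respiratory chain, -0.63 for heat shock, -0.26 for glutathione and thiol redox, -0.52 for the TCA cycle and 0.21 for anaerobic metabolism. With an estimated correlation the adjusted p was 0.0418 for RpoS genes and 0.0552 to 0.278 for the other 8. For the gshB minus gshA mutant they were -0.82 for ribosomal proteins, 0.51 for RpoS genes, -0.95 for purine and pyrimidine biosynthesis, -0.60 for heat shock and 0.54 for iron-sulfur cluster assembly, with adjusted p of 0.173 to 0.771 with an estimated correlation. The glutathione and thiol redox list holds frmR and frmA and the deleted genes gshA and gshB, and was not tested without them.

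Spots outside the measured genes gave signal above the local background. Spots named ara7 and ara23 (48 per slide) were above background in 89.8 % of readings in Cy3 and 11.3 % in Cy5, and internal control spots (274 per slide) in 96.0 % and 23.1 %.

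Other arrangements of the slides were counted for each comparison. Turning 1 slide of a strain makes 4 arrangements with the real one, too few for a share under 0.05. The real counts were 282, 303 and 752, in 1 of the 4 each, and the highest other count was 0 in each strain. For the mean response 1 of 100 arrangements of signs drawn from 256, the real one, gave 1196 genes, and the highest other gave 928. The signs were set partly from the agreement between slides of a strain, which other signs break, so these counts of signs do not bear on chance. The arrangement as labelled, which follows the dyes and was not among those drawn, gave 1251, more than the real one, and the value with a dye term was 2009. The 10 splits of 6 slides are too few for a share under 0.05. Real counts of 0, 4 and 3 for the differences were reached in 10, 1 and 1 of the 10, with 0 as the highest other, and counts of 0 and 1 for untreated levels in 10 and 2 of the 10, with 1 as the highest other.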

How the results depend on the processing

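The dye term, the 6 slides with cadmium in Cy5, the lists as labelled and the Cy3 channel of every slide were chosen after seeing the data, and the cause of each change below was not tested except where a smaller fit shows it. Counts of genes follow in the order wild type, gshA mutant, gshB mutant, mean of the strains, gshA minus wild type, gshB minus wild type and gshB minus gshA, and were 282, 303, 752, 1196, 0, 4 and 3 as reported. Of the 357 values of whole comparisons under alternatives, 244 stayed within 1.5 times, 59 were higher, 53 lower and 1 lost its call. Of 2320 values of 86 named genes and comparisons, 2132 kept direction and call, 187 lost the call, 85 of them as labelled, and 1 reversed: nmpC in the wild type, -3.28 as reported, was 0.0158 as labelled. Calls were lost most often for mipA and purA (18 of 27 alternatives each), mtr (12), trpE, frmR and frmA in the gshB mutant minus wild type (9 each), pyrD (8) and gshB (7) in the wild type. With the fit as labelled included, the adjusted p of trpE, frmR and frmA there ranged up to 0.9999, and that of pyrD from 0.00626 to 0.890. The median over all genes lay within 0.063 (log2) of 0 in every setting, which the centring of each slide favours.

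Array weights gave 1362, 1458, 2166, 2765, 11, 157 and 178. A dye term gave 828, 935, 1558, 2009, 4, 79 and 93, and the 6 slides with cadmium in Cy5 gave 1292, 1344, 1872, 2609, 4, 38 and 14, where any dye effect counts as response. As labelled, with no slide turned, the counts were 189, 108, 145, 1251, 0, 0 and 0 in limma. Print-tip loess gave 505, 502 and 1139 for the strains, 0 for gshB minus wild type and 5 (1 up, 4 down, against 0 up and 3 down) for gshB minus gshA. With only the slides of the strains compared, which leaves fewer slides in the fit, the gshA mutant had 131 and gshB minus gshA 1. For the differences, gain 30 gave 2, 9 and 6, gain 60 gave 0 and 0 for those of the gshB mutant, and the mean over all gains 2 for gshA minus wild type and 6 for gshB minus gshA. For gshA minus wild type the foreground mean and median centring gave 2 each, and no background subtraction, log ratios scaled between slides and marked spots left out gave 1 each. For gshB minus gshA, normexp offset 16, eBayes with trend and robust, and plain background subtraction gave 1, and the last gave 0 for gshB minus wild type. At unadjusted p under 0.05 in limma as reported, the differences had 56, 285 and 269 genes.

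Leaving out 1 slide gave 110 to 333 for the wild type (152 without its slide 1, 110 without its slide 3), 114 to 342 for the gshA mutant (144 without its slide 1, 114 without its slide 2), 326 to 820 for the gshB mutant (351 without its slide 1, 326 without its slide 2) and 883 to 1316 for the mean. A strain then keeps 2 slides, and the pooled spread assumes that they vary like the others. Its dye orientations are then balanced unlike those of the other strains, so a dye effect no longer cancels in its differences. How far this moved the counts was not tested. The range was 0 to 2 for gshA minus wild type (2 without gshB mutant slide 3), 0 to 6 for gshB minus wild type (0 without any wild type slide or gshB mutant slide 1 or 2) and 1 to 6 for gshB minus gshA (1 without wild type slide 2 or 3, gshA mutant slide 2, or gshB mutant slide 1 or 2, and 6 without gshB mutant slide 3). Called lists for gshB minus gshA, 5 as reported, ranged from 5 to 10 (8 without gshA mutant slide 1, 10 without gshB mutant slide 3). Untreated levels ranged from 0 to 13 for gshA minus wild type (1, frmA, without gshA mutant slide 1, 13 without its slide 3) and 0 to 2 for gshB minus wild type (0 without wild type slide 2 or 3 or gshB mutant slide 1 or 2, 2 without gshA mutant slide 1). Untreated frmR, the 1 gene reported for gshB minus wild type, lost its call without any 1 slide of these strains (adjusted p of 0.0603 to 0.212).

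Lists called were 12, 12, 13, 12, 9, 9 and 5 as reported. As labelled, with no slide turned, they were 2, 8, 4, 6, 3, 3 and 2. With an estimated correlation they were 4, 4, 1, 4, 0, 1 and 0, in fry 0, 1 and 0 for the differences, and in fry's mixed test 19 for the mean and 1, 3 and 3 for the differences. Untreated levels of gshA minus wild type, 0 as reported with 122 at unadjusted p under 0.05 in limma, gave 2 with quantile normalization of the untreated channel alone, no background subtraction, gain 30 and gain 60, and 1 with a dye term and with the Cy3 channel of every slide. Those of gshB minus wild type, 1 as reported, gave 0 with the Cy3 channel of every slide. The level of gshB in its mutant differed by -1.14 at gain 30, against -2.65 as reported, and lost its call there (adjusted p = 0.080). At gain 30, 23.3 % of spots were not above background, and whether this lowered the difference was not tested.

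In the authors' deposited table, genes at an absolute log2 ratio of at least 1 numbered 1530 (195 up, 1335 down), 1094 (256 up, 838 down), 1661 (327 up, 1334 down), 1310 (224 up, 1086 down), 286 (214 up, 72 down), 545 (319 up, 226 down) and 543 (208 up, 335 down). From the slides they were 542 (284 up, 258 down), 525 (254 up, 271 down), 876 (432 up, 444 down), 577 (281 up, 296 down), 90 (36 up, 54 down), 331 (125 up, 206 down) and 336 (135 up, 201 down). With each column of the table centred on its median they were 804 (455 up, 349 down), 755 (436 up, 319 down), 1143 (640 up, 503 down), 780 (471 up, 309 down), 225 (123 up, 102 down), 508 (232 up, 276 down) and 538 (277 up, 261 down), so the excess of falls in the table goes with its medians below 0.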

Other observations

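Operon groups in this part were chosen after their values were seen, and no test of them was planned. The ars genes, for arsenite export and its regulator, rose in all 3 strains. In the wild type, gshA and gshB mutant, arsC stood at 3.83, 4.81 and 3.60, arsB at 3.27, 3.97 and 2.55 and arsR at 2.48, 2.86 and 2.83 (log2), and each passed in each strain. A dye term left 2 of them lower in the gshB than in the gshA mutant, against 0 without it. Of 9 taurine and sulfonate uptake genes, 1 rose in the wild type, 5 in the gshA mutant and 4 in the gshB mutant, with tauA at 3.23, 4.18 and 6.16, not above background in the untreated channel of 1 slide of each mutant, while 0 of the 9 differed between strains in limma. When a dye term was added 3, 7 and 6 rose, and tauA, tauC and tauD were higher in the gshB mutant than in the wild type (adjusted p = 0.0461, 0.0469 and 0.0350). Of 7 trp and mtr genes, 5 rose in the wild type and 5 in the gshA mutant, with medians of 2.53 and 3.31, while in the gshB mutant 0 rose and 1 fell, with a median of -0.53. The dye term gave 7 and 6 rises in the first strains and 3 falls in the gshB mutant, and 4 genes were lower in this mutant than in either other strain, against 1 and 2 without it. Of the 3 genes proV, proW and proX, of glycine betaine uptake, 0 passed in the wild type and 2 fell in each mutant, proV by 1.76 in the gshA mutant (adjusted p = 0.00770) and by 1.84 in the gshB mutant (adjusted p = 0.00356), while its difference from the wild type did not pass (-2.13, adjusted p = 0.713, and -2.22, adjusted p = 0.196). With a dye term both differences of proV passed (adjusted p = 0.0301 and 0.00662), as did that of proW in the gshB mutant (adjusted p = 0.0223).

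In untreated cells, compared across slides, RpoS genes had a median level of -1.06 (log2) in the gshA mutant relative to the wild type (camera adjusted p = 4.32e-22, and adjusted p = 0.0695 with an estimated correlation) and -0.39 in the gshB mutant (adjusted p = 2.12e-09, and adjusted p = 0.193 with an estimated correlation). Iron uptake genes stood at -0.25 and -0.45 (adjusted p = 0.00991 and 1.77e-10, and adjusted p = 0.586 and 0.193 with an estimated correlation). Ribosomal protein genes stood at 0.32 and 0.22 (adjusted p = 0.000744 and 0.00767, and adjusted p = 0.199 and 0.298 with an estimated correlation). In the gshA mutant SOS genes stood at 0.42 (adjusted p = 0.00160, and adjusted p = 0.148 with an estimated correlation) and TCA cycle genes at -0.56 (adjusted p = 0.000846, and adjusted p = 0.337 with an estimated correlation). In the gshB mutant cysteine and sulfate genes stood at 0.24 (adjusted p = 0.0329, and adjusted p = 0.824 with an estimated correlation) and glutathione and thiol redox genes at 0.15 (adjusted p = 0.0267, and adjusted p = 0.193 with an estimated correlation). The glutathione list holds frmR and frmA, at 4.42 and 4.47 in this comparison, and the deleted gshB, at -1.92. The list was not tested without them. The untreated channel also enters the ratios, so these levels and the differences of response of the same lists are not independent.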
